A study of Macaca mulatta with 12 samples.

How the data were processed

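The samples were post-mortem superior frontal gyrus of 12 male rhesus macaques, 6 fetal and 6 postnatal, with 1 array for each animal. Per the labels' protocols, total RNA was extracted with Trizol and labelled cRNA was hybridised to an Affymetrix Human Gene 1.0 ST array, a human design used here with macaque RNA. Mismatches between macaque transcripts and human probes can lower a signal, so a difference in level between rows is not read as a difference between transcripts. The choice of 1 row per gene, the removal of dim rows and the floor do rank rows by level, so a row that is dim from mismatches can be removed or raised there. In the exchange pairs only the change between the groups is informative. The authors deposited 1 table of 9630 rows and 12 columns, read here as log2 expression values. The base of the log is stated nowhere, and base 2 was inferred from the span of the values. Background correction, summarisation, normalization and the rule that chose the 9630 rows are not given in the sources used here. The submitters' processing notes name genome build hg 18, and no coordinates are printed. The array medians, from 3.98 to 4.38, show that the arrays were not quantile matched over these rows. Scanner files were not used here, so other background corrections were not run. No batch of the arrays is given in the sources used here, so none was included in the fits. The number of arrays is among the limits on the precision that can be stated.

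Gene names came from the platform annotation held by GEO. 8848 rows had 1 symbol, 229 had several and 553 had none, and rows with several or none were not named. 8607 of the 8848 symbols were also in a macaque gene table. 8785 genes had a row, and for the 52 genes with more than 1 row the row with the highest mean over the 12 animals was used. Groups and ages came from the labels. Animals are named by group and replicate, and replicate numbers follow accession order and pair nothing.

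Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values of all 9630 rows, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 12 animals shared 1 estimate of spread in every main fit, while some of the alternatives below used fewer animals. The comparisons were postnatal against fetal, a slope per 10 days within the fetal group, a slope per doubling of age within the postnatal group, and newborn (2 animals) against fetal and juvenile (4 animals, 182 days or older) against newborn. 32 gene lists were fixed before the data were examined, as were the tests, most other settings and the rule for named genes. The 27 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The measured part of a list ranged from 13 of 74 genes (oxidative phosphorylation) to 26 of 27 (axon growth and guidance). It was 6 of 21 for microglia, 12 of 28 for the cell cycle and 3 of 13 for chaperones. A list result covers the measured genes only. The score of a list is the mean over its genes of the log2 values centred over the 12 animals, and scores were compared by exact permutation of the animals, two-sided, a test added after the data were examined. Fry and this permutation test ask whether a list differs at all, not whether it differs more than other genes. The share of same-sign slopes was set against 100 permutations of the ages. 4 exchange pairs were tested by exact permutation, and the list scores' age slopes by all 720 orders of the ages.

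The rule for named genes took the 5 rises and 5 falls with the largest log2 difference among called genes whose groups did not overlap. In each list it took the 2 called members with the largest difference and the largest of the opposite direction, or the member with the smallest p where none was called. It also took both genes of each exchange pair. In each trend or stage comparison it took up to 5 called genes per direction, or the 2 with the smallest p per direction where none was called. Members of small counts that fall outside this rule, and the genes of lists too small to test, were chosen after their values were seen.

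The alternatives were quantile normalization, centring on array medians, removal of the dimmest 25 percent of rows, a floor at the 20th percentile of each array, eBayes with trend and robust, array weights, each animal left out in turn, juvenile animals only, age as a covariate, other age scales, fits of fewer animals, and the mean of all rows of a gene. The removal of the array with the highest median in each group was added after the data were examined.

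The scripts were tested on simulated data of 9630 rows with 200 changed. In the comparison of the groups, 2.5% of rows shifted by 0.5 log2 units, 85% of those shifted by 1 and 100% of those shifted by 2 were called. In the data 3197 rows were called between the groups, so the adjusted threshold was less strict there than with 200 changed rows. Differences under 0.5 were called in the data, such as CSPG5 at -0.34, so these shares do not carry over to the data. For the postnatal slope, 87.5% of rows with 0.2 per doubling were called. For newborn against fetal, 50% of rows shifted by 1 and 97.5% of those shifted by 2 were called, and for juvenile against newborn 50.5% and 95.5%. Over 8785 genes, 3 of 3 lists shifted by 0.5 were called and 0 others. The simulated rows were independent of each other. In the data the estimated correlation between genes of a list reached 0.505 in the comparison of the groups (astrocytes), so the simulation does not show how often lists are called wrongly here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.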

Results

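Gene expression was measured in the superior frontal gyrus, a region of the prefrontal cortex, of 12 male rhesus macaques that had died suddenly. Total RNA of each animal was hybridised to 1 Affymetrix array designed for human genes, and the table held 9630 rows per animal. 6 animals were fetal, at 72, 57, 53, 42, 35 and 30 days before birth. 6 were postnatal, at 1, 24, 182, 353, 479 and 831 days of age. The series text calls the postnatal animals newborn, although 4 of the 6 were at least 182 days old, so they were also examined as 2 newborn animals (1 and 24 days) and 4 juvenile animals. The array medians lay between 3.98 and 4.38 on the deposited log scale. The base of that log is not given in the sources used here. It is read as 2 because of the span of the values, from -0.86 to 10.6, and every fold change below rests on that reading. The number of arrays limits the precision.

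The first question was how far the 2 groups lay apart. The first principal component held 51.2% of the variance and separated all fetal from all postnatal animals. The fetus of 30 days before birth and the animal of 1 day lay between the other animals on that component, at -10.2 and 6.79, while the other 5 fetal animals lay between -35.8 and -22.5 and the other 5 postnatal animals between 25.3 and 37.5. Across rows, pairs of fetal arrays correlated with a median r of 0.967, pairs of postnatal arrays with 0.958 and pairs across the groups with 0.894. Rows are not independent replicates. The array of the 1-day animal correlated more closely with that of the 30-day fetus (r = 0.967) than with any other postnatal array (the closest, at 182 days, gave 0.962).

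**Figure D1:**
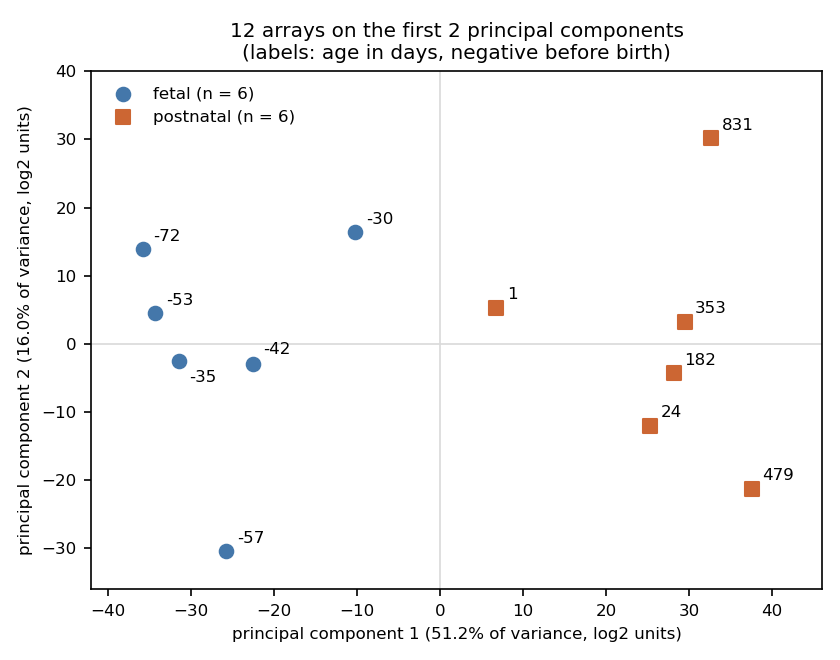
Each point is 1 array, placed by its first principal component (x axis, 51.2% of the variance) and its second (y axis, 16.0% of the variance), both in log2 units. The second component followed the array median (Pearson r = -0.894, Spearman's rho = -0.916), so array level may enter the y axis. Circles are the 6 fetal and squares the 6 postnatal animals, labelled with age in days, negative before birth; the 30-day fetus (-10.2) and the 1-day animal (6.79) lie between the other animals on the x axis.

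The main comparison set the 6 postnatal against the 6 fetal animals. The largest rises among genes whose groups did not overlap were in ETNPPL (row 8102249), an enzyme of ethanolamine phosphate breakdown, and MBP (row 8023889), a main protein of myelin. ETNPPL was at 0.57 ± 0.84 in fetal and 5.20 ± 0.92 in postnatal cortex (log2, mean ± SD, n = 6 each), a 24.8-fold difference. MBP was at 2.19 ± 0.49 and 6.36 ± 1.02, a 17.9-fold difference. PDYN (row 8064495), the precursor of the dynorphin opioid peptides, was 11.2-fold higher, TESPA1 (row 7963851) 10-fold and ERMN (row 8055969), a cytoskeletal protein of oligodendrocytes, 7.11-fold. The largest falls, again among genes whose groups did not overlap, were in the sodium channel SCN9A (row 8056491, 7.24-fold lower) and in DPYSL5 (row 8040725, 7.16-fold), a protein of growing neurites. Next were TRIM67 (row 7910503, 6.46-fold), the matrix protein POSTN (row 7971077, 6.33-fold) and NPR3 (row 8104746, 6.15-fold), the clearance receptor of natriuretic peptides. The limma adjusted p of these 10 genes lay between 1.81e-06 and 0.000129. All 6 fetal values of the 5 genes that rose lay under the 20th percentile of their arrays, so these folds depend on dim values. With a floor, that is with values under that percentile raised to it, MBP led with a log2 difference of 3.48, ETNPPL was at 2.33 (against 4.63), TESPA1 at 2.00 and PDYN at 1.60, while ERMN was at 0.55 and lost its call (adjusted p = 0.0835) and POSTN was at -1.45 (against -2.66). The falls depend on dim values too, since 5 of the 6 postnatal values of SCN9A, POSTN and NPR3 and all 6 of TRIM67 lay under the floor. With it SCN9A was at -2.40 (against -2.86), TRIM67 at -2.18 (against -2.69) and NPR3 at -2.07 (against -2.62).

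**Figure D2:**
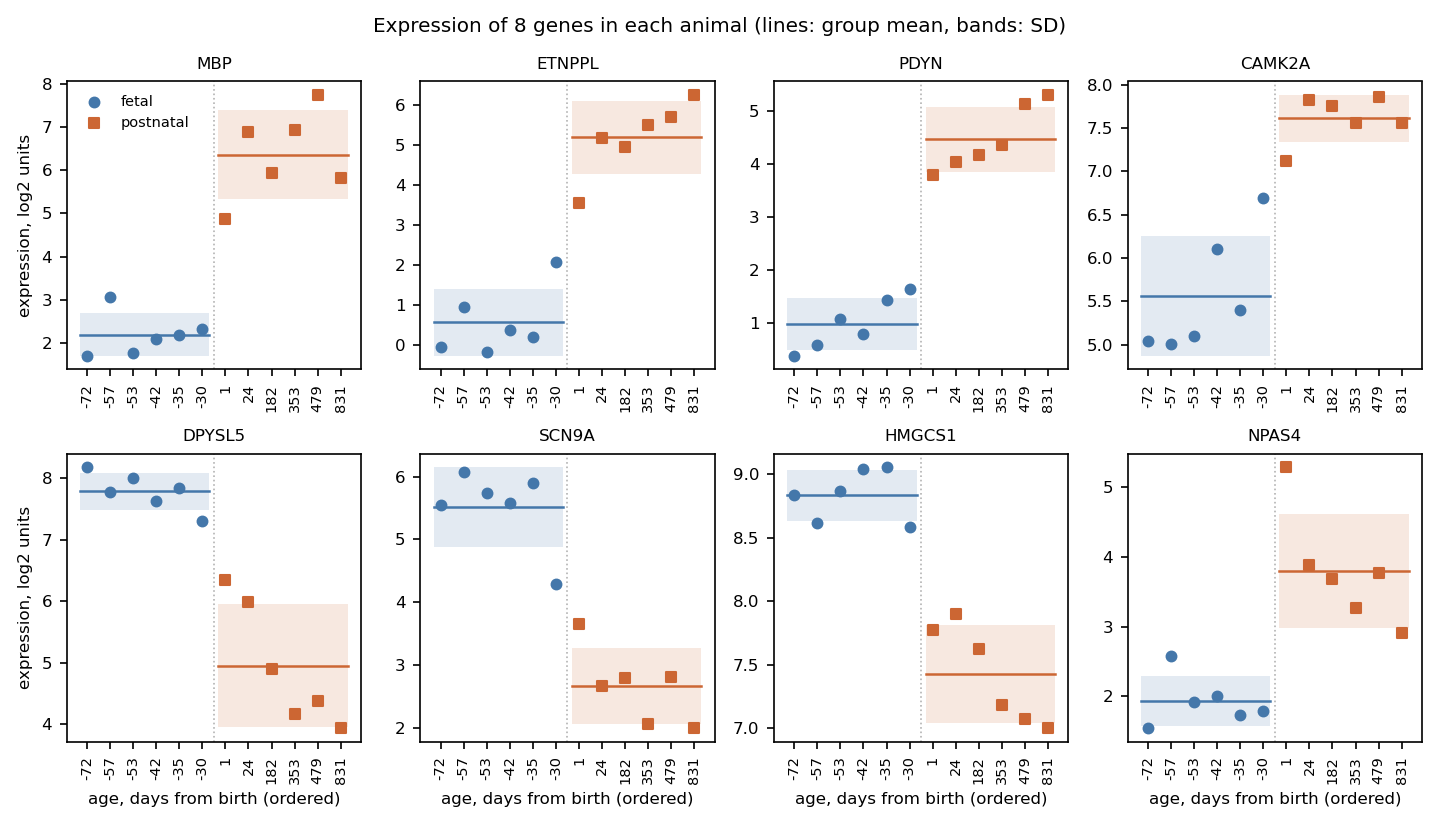
Each panel shows the expression of 1 gene (y axis, log2 units) in the 12 animals, ordered by age in days from birth (x axis, not to scale). Points are animals, lines the group means and bands the SD (n = 6 each); MBP, ETNPPL, PDYN and CAMK2A lie higher and DPYSL5, SCN9A and HMGCS1 lower in all 6 postnatal animals, and NPAS4 is highest in the 1-day animal.

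Of the 9630 rows, 1927 were higher and 1270 lower in postnatal animals (limma, adjusted p under 0.05), and 442 and 221 of these differed by at least 1 log2 unit. In 1299 rows the 6 values of one group all lay beyond the 6 of the other, 789 higher and 510 lower, where chance gives 0.216% of rows or 20.8 rows. The share of higher calls depended on the scaling between arrays. It was 60.3% on the deposited values, 45.2% with each array centred on its median (1699 higher, 2059 lower) and 48.1% after quantile normalization (1858 higher, 2004 lower). Of the 3197 rows called on the deposited values, 2956 were called in the same direction after centring and 3058 after quantile normalization. The median difference of all rows was 0.07 log2 units as deposited and -0.03 and -0.01 after centring and quantile normalization.

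Of 10 measured genes of the myelin and oligodendrocyte list, 9 rose and 1 fell, with a median difference of 1.77 log2 units. MBP and ERMN led the rise, and TSPAN2, a tetraspanin of oligodendrocytes, fell by 0.94. Of 13 astrocyte genes, 12 rose and none fell (median 1.17). S100B, a calcium-binding protein, rose by 1.95 ± 0.23 (log2 difference ± SE, n = 6 against 6) and GFAP, the intermediate filament of astrocytes, by 1.94 ± 0.27. Of 6 microglial genes, 4 rose (median 0.66), led by the receptors GPR34 (1.07 ± 0.20) and CSF1R (1.05 ± 0.20), with P2RY12 and TYROBP the others. All 12 values of GPR34 lay under the 20th percentile of their arrays. The list of oligodendrocyte precursors moved the other way, with 2 of 6 genes lower (median -0.27). These were PCDH15, which fell by 0.78, and CSPG5, which fell by 0.34.

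The camera test with its preset correlation called these 4 lists, with adjusted p of 9.96e-05 for myelin, 5.78e-07 for astrocytes, 0.0266 for microglia and 0.0482 for precursors. None was called with an estimated correlation, where adjusted p = 0.297 for each of the first 3 lists and adjusted p = 0.365 for precursors. The mean score of each of the first 3 lists was higher in all 6 postnatal than in all 6 fetal animals (exact permutation test, two-sided, p = 0.00216, the smallest that 6 against 6 can give, and 0.00584 adjusted over 27 lists). The microglial call was lost without the 1-day animal (postnatal replicate 1, adjusted p = 0.0514), without the dimmest 25 percent of rows (0.0963) and with the floor (0.0929), where GPR34 was at 0.12 (adjusted p = 0.465), the difference between the floors. With the floor the myelin median was 1.00, and the list kept its call. The precursor call was lost without fetal replicate 1 or 3 or postnatal replicate 1, 3, 4 or 5 (adjusted p up to 0.118) and after quantile normalization (0.053) and in 6 other settings (up to 0.0991). CSPG5 lost its call without fetal replicate 3, 4, 5 or 6 or postnatal replicate 1, 3, 4, 5 or 6 (adjusted p up to 0.0945).

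Of 25 presynaptic genes, 17 rose and 2 fell (median 0.67). SNAP25, a protein of the vesicle fusion machinery, rose by 1.42 ± 0.22 log2 units. SLC17A6, a vesicular glutamate transporter, fell by 1.35, and SYN3, a synapsin, by 0.81. Of 23 genes of the postsynaptic density, 12 rose and none fell (median 0.50). CAMK2A, a calcium-dependent kinase of excitatory synapses, rose by 2.05 ± 0.26, from 5.56 ± 0.69 to 7.61 ± 0.27 (mean ± SD, n = 6), and the scaffold gene DLGAP3 by 1.44 ± 0.22, or by 0.49 with the floor, under which its 6 fetal values lay. In camera, adjusted p was 0.000111 and 0.00784, against adjusted p = 0.315 and 0.511 with an estimated correlation. All 6 postnatal animals scored above all fetal animals on both lists (exact permutation p = 0.00216, adjusted 0.00584). In the same animals the astrocyte score was higher by 1.19 and the myelin score by 1.73.

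**Figure D3:**
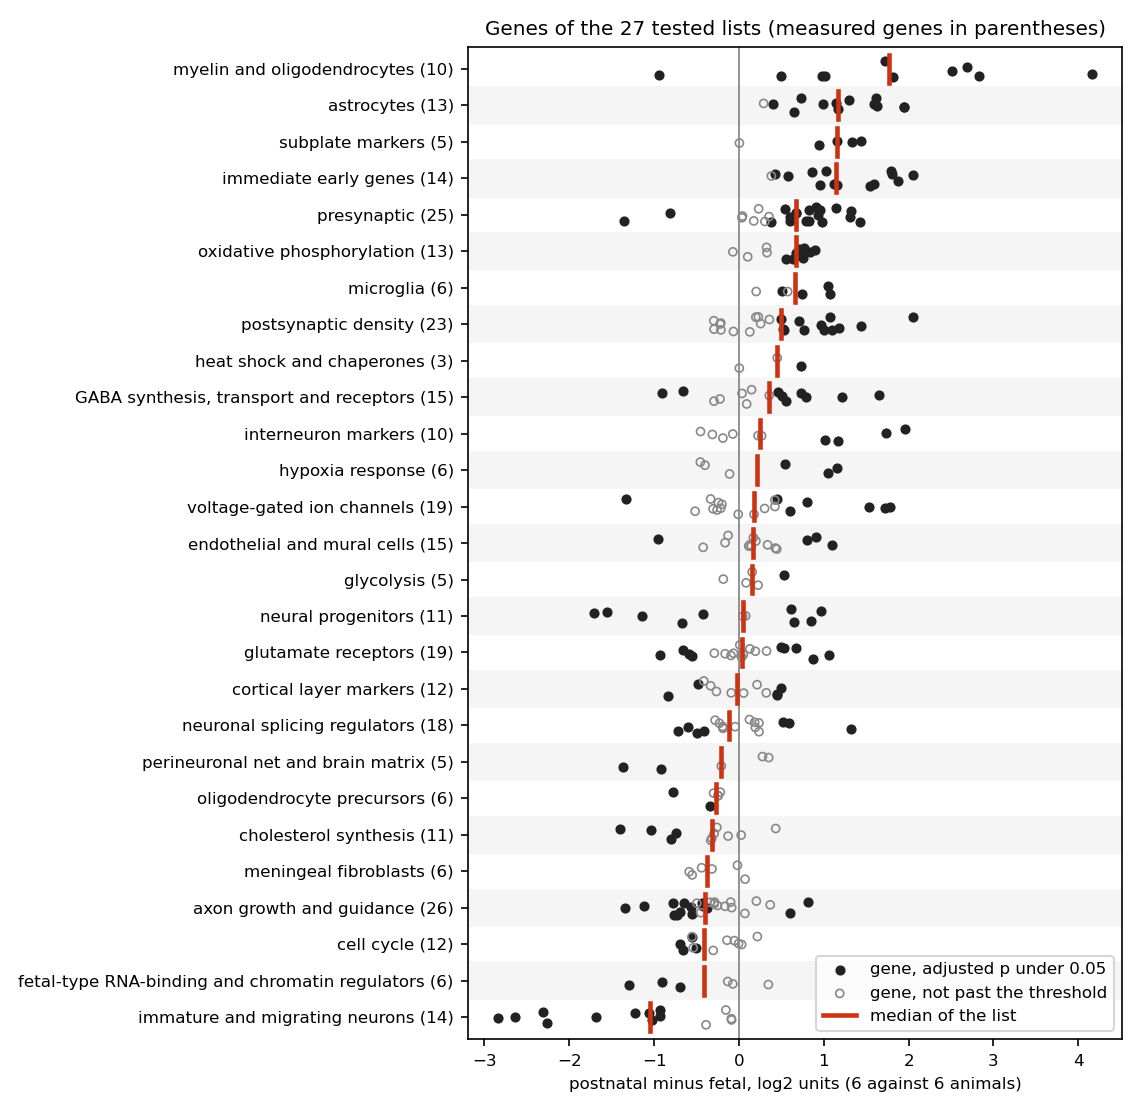
Each point is 1 gene, placed by its difference between 6 postnatal and 6 fetal animals (x axis, log2 units) and its list (y axis, 27 lists with the number of measured genes). Filled points passed adjusted p 0.05 and red bars are list medians, from 1.77 for myelin and oligodendrocytes to -1.05 for immature and migrating neurons.

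Receptors and channels moved in both directions, and none of their lists was called by camera. Of 19 glutamate receptor genes, 5 rose and 4 fell, with GRIN2A, an NMDA receptor subunit, up by 1.07 and GRM7, a metabotropic receptor, down (a fall by 0.93). The median of that list was 0.03 while its test pointed down (adjusted p = 0.624), and the median was -0.07 after centring and -0.02 after quantile normalization. Over all settings it lay between -0.07 (juvenile postnatal animals only) and 0.16 (without postnatal replicate 3), and it was also negative without fetal replicate 6 (-0.02) or postnatal replicate 1 (-0.004) or 2 (-0.05). Of 15 genes of GABA synthesis, transport and receptors, 7 rose and 2 fell (adjusted p = 0.353). The receptor subunit GABRD rose by 1.66 (0.87 with the floor) and GAD2, an enzyme that makes GABA, by 1.21, while the transporter SLC6A11 fell by 0.90 and the receptor subunit GABRA3 by 0.67. Of 10 interneuron markers, 4 rose (adjusted p = 0.252). The calcium-binding proteins CALB1 and PVALB rose by 1.96 ± 0.23 and 1.74 ± 0.25, but PVALB, with all 6 fetal and 3 postnatal values under the floor, was at 0.49 with it (adjusted p = 0.0382). The neuropeptides NPY and VIP were the others. Of 19 voltage-gated channel genes, 6 rose and 1 fell (adjusted p = 0.49). KCNAB2, a potassium channel subunit, rose by 1.78, SCN2B, a sodium channel subunit, by 1.72, and SCN3A, a sodium channel, fell by 1.33. The score of these last 3 lists was higher in postnatal animals by an exact permutation test adjusted over 27 lists, with adjusted p of 0.0209, 0.0135 and 0.0481.

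Of 14 measured genes of immature and migrating neurons, 10 fell and none rose (median -1.05). DPYSL5 was at 7.79 ± 0.31 in fetal and 4.95 ± 1.01 in postnatal animals (mean ± SD, n = 6). ST8SIA2, the enzyme that adds polysialic acid to cell surface proteins, fell by 2.64, from 6.62 ± 0.75 to 3.98 ± 1.03. Of 26 genes of axon growth and guidance, 12 fell and 2 rose (median -0.40). The guidance receptor ROBO1 fell by 1.34 and STMN2, a regulator of microtubules, by 1.12, while the adhesion molecule CNTN2 rose by 0.81 (0.59 with the floor) and the guidance ligand SLIT3 by 0.61. In camera, adjusted p was 2.11e-08 and 0.000111, and adjusted p = 0.297 for both with an estimated correlation. The immature-neuron score was lower in all 6 postnatal than in all fetal animals (exact permutation p = 0.00216) and the axon score was lower with an exact permutation p = 0.00433. The astrocyte, microglial and myelin scores moved the opposite way in these animals.

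Of 11 measured genes of neural progenitors, 5 fell and 4 rose, and camera made no call (adjusted p = 0.486), while the exact permutation test of the score did (a difference of -0.211, adjusted p = 0.0292). The median of the list was 0.04, and its test and mean pointed down. The sign of the median depended on the setting, with -0.42 without the dimmest 25 percent of rows (adjusted p = 0.324), -0.07 with juvenile postnatal animals only, -0.06 after quantile normalization, -0.05 after centring, -0.03 and -0.01 without postnatal replicate 1 or 3, -0.002 with array weights and 0.09 without postnatal replicate 5. PROM1, a membrane protein of neural stem cells, fell by 1.71 and FABP7, a lipid carrier of radial glia, by 1.55, with TNC, VIM and PTPRZ1 the other falls. HOPX rose by 0.96, with GLI3, PAX6 and LIFR the other rises. Of 12 cell cycle genes, 4 were lower (median -0.41, adjusted p = 0.024, adjusted p = 0.511 with an estimated correlation, exact permutation p of the score 0.0628). These were TYMS (-0.69 ± 0.24), TOP2A (-0.66 ± 0.22), CCNA2 and MCM6, which all serve DNA replication or division. Of 6 fetal-type RNA-binding and chromatin regulators, 3 were lower, namely IGF2BP3 (-1.30), EZH2 (-0.91) and TET1 (-0.70). The median of that list was -0.41, with adjusted p = 0.0392 and adjusted p = 0.298 with an estimated correlation.

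When values under the 20th percentile of each array were raised to it, TYMS and TOP2A both went to 0.12, since all 12 values of each lay under the floor and only the floors differed. HOPX, IGF2BP3 and EZH2 lost their calls, as did the cell cycle list (adjusted p = 0.62) and the list of fetal-type regulators (median -0.14, adjusted p = 0.235). Without the dimmest 25 percent of rows these lists had medians of -0.05 and -0.13 and no call (0.498 and 0.39). TYMS lost its call without fetal replicate 2, 3 or 6 or postnatal replicate 2, 3 or 6 (adjusted p up to 0.0725), and TOP2A without fetal replicate 2, 3, 4 or 6 or postnatal replicate 3, 4 or 6 (up to 0.0733). The list of fetal-type regulators lost its call without postnatal replicate 3 or 4 (adjusted p up to 0.0541), after quantile normalization (0.0522), after centring (0.0585) and with array weights (0.055).

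Of 5 subplate markers, 4 rose (median 1.15, adjusted p = 0.0116, adjusted p = 0.315 with an estimated correlation). They were NR4A2 (1.44 ± 0.20), CCN2 (1.33 ± 0.20), MOXD1 and KCNAB1. NR4A2 is a nuclear receptor that neuronal activity also induces, and CCN2 is a secreted protein that stress and stretch also induce. Of 12 cortical layer markers, 3 rose and 2 fell (adjusted p = 0.537), with POU3F2, a transcription factor of upper layers, lower by a fall of 0.83 and LMO4 the other fall. RASGRF2, ETV1 and NTNG2 were higher. RASGRF2 (0.50 ± 0.18) lost its call after centring (adjusted p = 0.0643) and without fetal replicate 3, 4, 5 or 6 or postnatal replicate 2, 4, 5 or 6 (up to 0.0898). Of 5 genes of the perineuronal net and brain matrix, 2 fell (adjusted p = 0.342), the proteoglycan VCAN by 1.37 and the link protein HAPLN1 by 0.92. HAPLN1 was at -0.59 with the floor and lost its call without the array of highest median in each group (-0.87, adjusted p = 0.0573), a setting chosen after seeing the data. Of 18 neuronal splicing regulators, 3 rose and 4 fell (adjusted p = 0.486). MBNL2 rose by 1.32 and CELF2 fell by 0.72, with MBNL1 and RBFOX3 the other rises and PTBP2, KHDRBS2 and RBFOX2 the other falls. The median of the splicing list was -0.12 and its mean 0.0026. The median was -0.21 after centring, -0.18 without postnatal replicate 2, -0.08 without fetal replicate 4, -0.05 without postnatal replicate 3, -0.04 without the dimmest 25 percent of rows and -0.005 with the floor.

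Of 13 measured genes among the 74 listed for oxidative phosphorylation, 9 rose and none fell (median 0.67, adjusted p = 0.00103, adjusted p = 0.297 with an estimated correlation). NDUFS3, a subunit of complex I, rose by 0.90 ± 0.17 and CYC1, cytochrome c1, by 0.84 ± 0.16. All 6 postnatal scores exceeded all fetal scores (exact permutation p = 0.00216). Of 11 genes of cholesterol synthesis, 4 fell and none rose (median -0.32, adjusted p = 0.00974, adjusted p = 0.455 with an estimated correlation, exact permutation p of the score 0.0325 and 0.0487 adjusted). HMGCS1, an early enzyme of the pathway, fell by 1.41, from 8.83 ± 0.20 to 7.43 ± 0.39 (mean ± SD, n = 6), and DHCR7, the enzyme of a last step, by 1.04, with MSMO1 and SQLE the other falls. DHCR7 lost its call without the array of highest median in each group (-0.91, adjusted p = 0.056), and the list median was -0.75 without the dimmest 25 percent of rows. The myelin score rose in the same animals by 1.73. Of 5 glycolytic genes 1 rose, the neuronal enolase ENO2, by 0.53 (list adjusted p = 0.49).

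Immediate early genes are transcription factors and other genes that cells switch on within minutes of stimulation. Of 14 measured, 13 rose and none fell (median 1.14, adjusted p = 4.27e-07, adjusted p = 0.297 with an estimated correlation). EGR1 rose by 2.05 ± 0.28, from 2.92 ± 0.76 to 4.97 ± 0.33 (mean ± SD, n = 6), and NPAS4 by 1.88 ± 0.30. With the floor, under which all 6 fetal values of NPAS4 lay, NPAS4 was at 0.925 and the list median at 0.75, and both kept their calls. All 6 postnatal scores exceeded all fetal scores (exact permutation p = 0.00216). Genes of 2 stress responses were measured beside them. Of 6 hypoxia genes 3 rose, namely EGLN3 (1.15 ± 0.19), BNIP3 (1.05 ± 0.16) and PDK1, and of 3 chaperones 1 rose, HSPA5 (0.73 ± 0.19). Neither list was called by camera (adjusted p = 0.486 and 0.384), and their scores were higher by 0.298 and 0.397 (exact permutation p = 0.0368 and 0.00433, adjusted 0.0523 and 0.00974).

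Of 15 genes of endothelial and mural cells, 3 rose and 1 fell (adjusted p = 0.486). RGS5, a marker of pericytes, rose by 1.09, with SLC2A1 and ABCB1 the other rises, and the receptor KDR fell by 0.95. Of 6 genes of meningeal fibroblasts none passed the threshold (median -0.38, adjusted p = 0.187), and ASPN, the one with the smallest p, differed by -0.59 (adjusted p = 0.0952). That list was called without the 24-day animal (postnatal replicate 2, median -0.57, adjusted p = 0.0369) and with juvenile postnatal animals only (median -0.60, adjusted p = 0.0477), where ASPN was called too (-0.80, adjusted p = 0.0432). The list was not called with an estimated correlation (adjusted p = 0.543) or with the floor (median -0.10, adjusted p = 0.273). For the last 5 lists fewer than 3 genes were measured and no list test was made. TTR of the choroid plexus differed by 0.24 (adjusted p = 0.404), ALAS2 of red cells by -0.36 (0.196) and CD2 of leukocytes by 0.13 (0.557). The ribosomal genes RPL12 and RPS7 differed by -0.06 (0.835) and 0.46 (0.22). B2M, the light chain of class I antigen-presenting molecules, rose by 1.96 ± 0.21 and the interferon-induced IFIT1 by 1.74 ± 0.38. IFIT1 was dim in fetal animals (2.25 ± 0.61, mean ± SD) and was not examined with the floor.

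Over the 27 tested lists camera called 8 higher and 6 lower with the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.297). Without the dimmest 25 percent of rows or with the floor 3 lists were lower. The preset calls should be read beside other splits of these animals into 6 and 6, of which 99 were drawn. They called a median of 5 lists and up to 13. The split with 13 lists had 4 fetal animals on 1 side, so it carried part of the group difference. With the self-contained test fry 13 of the 14 called lists were called (the exception was cell cycle, adjusted p = 0.0974) and 4 further lists, and the exact permutation test of the scores also called 13, with cell cycle again the exception, and 5 further lists. With 3197 of the 9630 rows called, many lists can pass these 2 tests. They do not show that a list moved more than other genes. Adjusted over the list alone, counts differed from those given above in 11 lists, and were equal in the other 16. The presynaptic list had 19 rises adjusted over the list alone, the postsynaptic list 13 rises and 1 fall, the oxidative phosphorylation list 10 rises and the channel list 8 rises and 2 falls. The microglial list had 5 rises, the chaperones 2 rises, the immature-neuron list 11 falls, and the cell cycle list 5 falls. The GABA list then had 3 falls, and the glutamate receptor list 5 falls and the hypoxia list 1 fall.

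**Figure D4:**
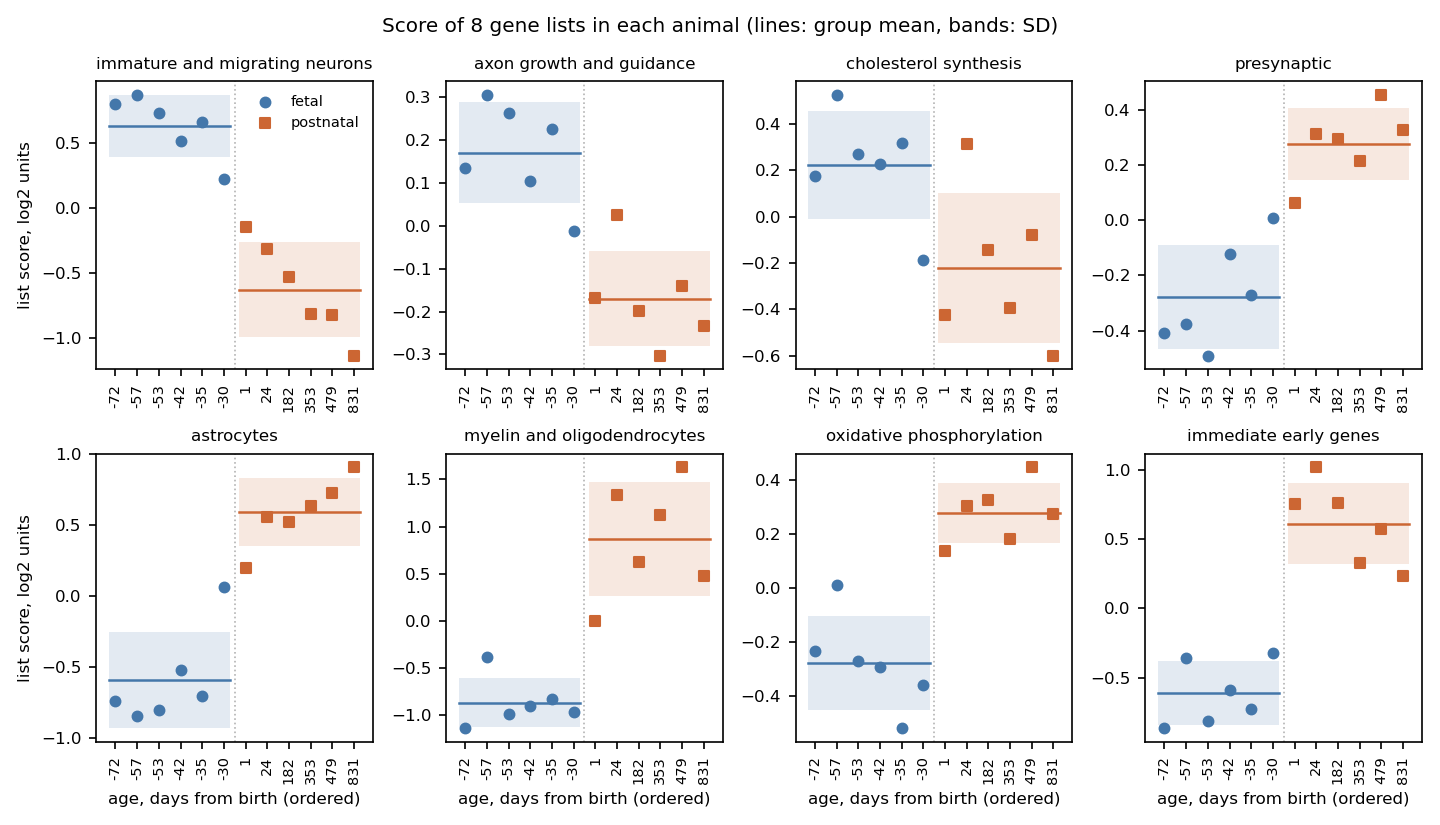
Each panel shows the score of 1 gene list (y axis, mean log2 value of its genes, each centred over the 12 animals) by animal, ordered by age in days from birth (x axis, not to scale). Points are animals, lines group means and bands the SD (n = 6 each); the myelin score rose by 1.73 and the immature-neuron score lay higher in all 6 fetal animals.

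Known exchanges of an earlier for a later form of a protein were tested as the difference between the 2 genes of a pair within each animal. For the NMDA receptor subunits GRIN2B and GRIN2A, GRIN2A minus GRIN2B was -2.26 ± 0.33 in fetal and -0.54 ± 0.28 in postnatal animals (log2, mean ± SD, n = 6), a change of 1.72. The change was 1.51 for the sodium channels SCN3A and SCN1A and 1.5 for the matrix proteins TNC and TNR, and in these 3 pairs all postnatal values lay above all fetal values (exact permutation test, two-sided, p = 0.00216, adjusted over 4 pairs 0.00289). For the chloride transporters SLC12A2 and SLC12A5 it was 1.01, with 4 of 6 postnatal values above all fetal ones (exact permutation p = 0.00866, adjusted 0.00866). The pairs reached this in different ways. GRIN2A rose by 1.07 and GRIN2B fell by 0.66, and SLC12A5 rose by 1.35 while SLC12A2 differed by 0.33 (adjusted p = 0.0764). SCN3A fell by 1.33 and TNC by 1.15, while SCN1A differed by 0.18 (0.343) and TNR by 0.35 (0.147). TNR was called without postnatal replicate 3 (adjusted p = 0.0377) and SLC12A2 without postnatal replicate 6 (0.05). Levels of 2 genes on an array are not on a common scale, so only the change of each difference is informative.

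Within the fetal group, expression was set against days before birth. No row passed the threshold (limma, smallest adjusted p = 0.419), and 538 rows had an unadjusted p under 0.05. The genes with the smallest p in each direction are given as values. PTH2R, a receptor of the parathyroid hormone family, had a slope of -0.50 ± 0.09 log2 units per 10 days towards birth (SE, adjusted p = 0.419), and BMPR1B, a receptor of bone morphogenetic proteins, 0.30 ± 0.06 (adjusted p = 0.419). PSMB6, a proteasome subunit, had -0.36 ± 0.07 (adjusted p = 0.419) and the kinase PDK3 0.34 ± 0.08 (adjusted p = 0.755). With the floor the slopes of BMPR1B and PDK3 were 0.09 and 0.11. With the preset correlation camera called 13 lists, 9 of them rising towards birth, and with an estimated correlation 0 (smallest adjusted p = 0.221). By an exact permutation test of the list scores against age no list passed after adjustment (smallest adjusted p = 0.225). In simulated data of the same size, 67.5% of rows with a slope of 0.4 per 10 days were called and 0% of those with 0.2.

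Within the postnatal group, expression was set against the log2 of age. 4 rows rose and 2 fell (limma), and 821 rows had an unadjusted p under 0.05. CRYAB, a small heat-shock protein of oligodendrocytes and astrocytes, rose by 0.28 ± 0.04 log2 units per doubling of age (SE, adjusted p = 0.0256). PLAAT3, a phospholipase, rose by 0.25 ± 0.03, the zinc finger gene ZNF483 by 0.20 ± 0.03 and the matrix protein EFEMP1 by 0.18 ± 0.03. DPYSL5 fell by 0.26 and PLPPR1, a membrane protein of growing neurons, by 0.15. Without the 1-day animal the slope of CRYAB was 0.45 (adjusted p = 0.0654) and that of DPYSL5 -0.41 (0.0289). The immature-neuron score fell with age, with a slope of -0.09 and Spearman's rho of -1 (exact permutation p = 0.00139, adjusted over 27 lists 0.0375). In camera 6 lists were called, 4 rising and 2 falling, and 0 with an estimated correlation (smallest adjusted p = 0.224). No row was called without fetal replicate 2 or without postnatal replicate 4 or 5, 1 without postnatal replicate 2, and 3 without fetal replicate 3 or 6 or postnatal replicate 1. No row was called with array weights or in a fit of the postnatal animals alone, and 29 were called after quantile normalization, 27 after centring, 31 with the floor, 39 with trend and robust in eBayes, 24 with the rank of age and 42 with age in days.

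The 2 newborn animals were compared with the 6 fetal animals, in a fit where all 12 animals share 1 estimate of spread. 474 rows were higher and 216 lower in the newborns. These 690 calls depended on the scaling, with 1170 after quantile normalization and 1090 after centring. ETNPPL was 14.0-fold higher (3.81 ± 0.52, log2 ± SE), MBP 12.8-fold, PDYN 7.68-fold, TESPA1 6.92-fold and the activity-induced transcription factor NPAS4 6.33-fold. SCN9A was 5.13-fold lower, TRIM67 4.57-fold, PTH2R 4.32-fold, the prolactin receptor PRLR 4.08-fold and the actin regulator AVIL 3.90-fold. Adjusted p of these 10 genes lay between 0.000586 and 0.0161. Of 14 immediate early genes 10 rose, and 12 adjusted over the list alone (median 1.43, camera adjusted p = 2.83e-12, adjusted p = 0.113 with an estimated correlation). Camera called 13 lists in all, 9 higher and 4 lower, and 0 with an estimated correlation.

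Without the 24-day animal (postnatal replicate 2) 2 rows were called, and without the 1-day animal (postnatal replicate 1) 785. Of the 10 genes named, only TESPA1 and NPAS4 kept their calls without the 24-day animal. ETNPPL then differed by 3 log2 units (adjusted p = 0.12) and MBP by 2.67 (0.124), while PDYN (2.82 against 2.94, adjusted p = 0.0576) and TRIM67 (-2.33 against -2.19, adjusted p = 0.12) lost their calls with little change in the difference. The count was 1061 without fetal replicate 1, 415 without fetal replicate 3, 418 without fetal replicate 5 and 366 without fetal replicate 6. With low values raised to the 20th percentile of each array, MBP was at 3 log2 units, NPAS4 at 1.71, ETNPPL at 1.5, TESPA1 at 1.47 and PDYN at 1.05, all still called. SCN9A was at -2.14, TRIM67 at -2.18 and PTH2R at -1.85, still called as well. PRLR went to 0.01 and AVIL to -0.84, and both lost their calls (adjusted p = 0.973 and 0.127).

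The 4 juvenile animals differed from the 2 newborns in 4 rows (limma, with 674 rows at an unadjusted p under 0.05). CRYAB was 3.90-fold higher in juveniles, DPYSL5 3.56-fold lower and TNC 3.04-fold lower (adjusted p = 0.0442 each). The other call was row 8125919, which is annotated with several genes (1.30 ± 0.21, higher). No row was called without fetal replicate 2, 3 or 6 or postnatal replicate 1, 2, 3, 4 or 5, 1 was called without fetal replicate 1, and 8 without postnatal replicate 6. No row was called with array weights or in a fit of these 6 animals alone, and TNC lost its call after centring (adjusted p = 0.0613), where 2 rows were called. The count was 7 without the dimmest 25 percent of rows, 13 with the floor and 10 with trend and robust in eBayes. In camera 10 lists were called, 8 of them lower in juveniles, and 0 with an estimated correlation (smallest adjusted p = 0.413). The perineuronal net and brain matrix list was among the lower ones, with 0 of 5 genes lower over all rows, 2 adjusted over the list alone, and a median of -0.47 (camera adjusted p = 0.00475, adjusted p = 0.413 with an estimated correlation).

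The last question was whether rows that differed between the groups also changed with age within a group. Of the 3197 called rows, 83.9% had a postnatal slope with the sign of the group difference (permutation of the ages, 100 draws, p = 0.0099, the smallest these draws can give). The share was 83.7% among rows that rose and 84.3% among rows that fell. Permuted ages gave shares from 20.9% to 83.5%. Without the 1-day animal (postnatal replicate 1) the share was 57.1% (permutation p = 0.416), and it lost its call without postnatal replicate 2 (84.9%, p = 0.0693) or 4 (81.1%, p = 0.0891) and with the rank of age in place of its log2 (78.6%, p = 0.099). In the fetal group the share was 74.4%, inside the range of 15.7% to 82.6% that permuted ages gave (permutation p = 0.158).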

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

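The tests of array levels, of array quality, of the stress score between the groups and of the presynaptic score were chosen after the results were seen, while the animal-by-animal test and the splits were set before. An animal was singled out where its gap to the nearest of the other 5 in its group, as a share of the group's range, passed Dixon's 95% limit. That was so in 2 of 54 list scores and 9 of 162 tests of named genes, where chance gives about 1 in 20. Fetal replicate 1, at 30 days before birth, held 6 of the 11. Its astrocyte score was 0.06 against -0.85 to -0.52 in the other fetuses (gap share 0.642), and GFAP was 7.24 against 5.35 to 5.85 (0.734). MBNL2 was 5.59 against 5.14 to 5.26 (0.731). SCN9A was 4.29 against 5.54 to 6.07 (0.703), ST8SIA2 5.15 against 6.56 to 7.19 (0.687) and VCAN 4.20 against 5.34 to 6.02 (0.629).

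Fetal replicate 4 had ERMN at 0.97 against -0.10 to 0.26 (0.662) and GRIN2B at 7.19 against 7.79 to 8.05 (0.695). Postnatal replicate 2, at 24 days, had a meningeal fibroblast score of 0.50 against -0.46 to -0.21 (0.74). FABP7 in postnatal replicate 4 was 5.78 against 6.48 to 6.68 (0.774), and SCN3A in postnatal replicate 3 was 4.51 against 5.28 to 5.63 (0.685). None of the 27 lists had fetal and postnatal slopes that differed after adjustment (smallest adjusted p = 0.275, with 4 lists at an unadjusted p under 0.05).

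The fetus of 30 days before birth and the 1-day animal lay between the other fetal and postnatal animals. On rows called between fetal and juvenile animals with the placed animal left out, they were 34.5% and 55.5% of the way from the fetal to the juvenile mean, where the other fetuses lay between -13.8% and 9.88% and the other postnatal animals between 81.5% and 101%. Unequal array levels are argued against, since after quantile normalization the positions were 36.3% and 56.1%. Poor arrays stay open. With these 2 arrays left out as partners, the highest correlation with an array of the own group was 0.97 for the 30-day fetus, against 0.967 to 0.981 for the other fetuses, and 0.962 for the 1-day animal, against 0.961 to 0.971 for the other postnatal animals, so both lay in the lower part of the range. That these animals may be part of a gradual change around birth is a hypothesis that remains open, as does a difference between single animals.

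The immediate early genes were higher in postnatal animals by a median of 1.14. Unequal array levels are argued against as the cause, since the median was 1.04 after quantile normalization. The list kept its camera call there with the preset correlation, but on the deposited values it was not called with an estimated correlation (adjusted p = 0.297). Stress of the tissue around death stays open, since a score of 9 hypoxia and heat-shock genes was higher in postnatal animals by 0.331 (exact permutation p = 0.0195, 6 of 9 genes higher). Animal by animal within the groups the 2 scores correlated with r = 0.62 over 12 animals (permutation p = 0.0519, rank correlation 0.686 with p = 0.0283, r = 0.73 without the 2 farthest animals), which leaves this open. A biological difference between the ages is also open and untested.

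The immature-neuron genes were lower in postnatal animals by a median difference of -1.05. Unequal array levels are argued against, since the median was -1.11 after quantile normalization. A lower share of neuronal RNA stays open. The presynaptic score was higher in postnatal animals by 0.555, but it also follows the level of these genes within each neuron, so it cannot decide this. The astrocyte and myelin scores were higher as well, by 1.19 and 1.73. Maturation of neurons may contribute, as a hypothesis that was not tested, and a change in the makeup of the neurons stays open.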

How the results depend on the processing

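Only the removal of the array with the highest median in each group was chosen after the data were examined. For named genes, 1747 of 1888 comparisons with an alternative kept direction and side of the threshold, 135 lost the call, 3 gained one and 3 reversed. For lists these were 601 of 647, 40, 6 and 0. The direction of a list is that of its test, so a median that changed sign does not count as a reversal. With the floor the cell cycle median went from -0.408 to 0.117 and was counted as a lost call. The 3 reversals came with values under the 20th percentile of each array raised to it: TYMS 0.117, TOP2A 0.117 and, in newborns against fetuses, PRLR 0.0137. All 12 values of TYMS and TOP2A lay under the floor, so 0.117 is the difference between the floors of the groups, and dim signals limit these genes. For the other changes below the cause was not tested.

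Quantile normalization gave 2004 rows lower in postnatal animals, 29 rows with a postnatal trend and 1170 between newborn and fetal animals. Median centring gave 2059, 27 and 1090, and 2 rows between juvenile and newborn animals. Without the dimmest 25 percent of rows, 7 rows differed between juvenile and newborn animals and 3 lists were lower. With the floor these were 13 and 3, and 31 rows had a postnatal trend. Postnatal trend and juvenile against newborn gave 39 and 10 rows with trend and robust in eBayes, and 0 and 0 with array weights. Without the arrays of highest median, TOP2A, CSPG5 and RASGRF2 lost their calls (adjusted p = 0.0951, 0.102 and 0.134) and juvenile against newborn gave 0 rows, as did a fit of only the stages compared (0). With juvenile animals only, TYMS lost its call (adjusted p = 0.0929) and ASPN gained one (0.0432). With an estimated correlation 0 lists were higher and 0 lower. The postnatal trend gave 0 rows in a fit of that group alone, 24 with the rank of age and 42 with age in days. The share of same-sign postnatal slopes was 78.6% with the rank of age (permutation p = 0.099).

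With each animal left out in turn, rows higher in postnatal animals ranged from 1597 to 2208 and rows lower from 1047 to 1415, lists higher from 7 to 8 and lists lower from 4 to 7. The postnatal trend ranged from 0 to 9 rows, newborn against fetal from 2 to 1061 and juvenile against newborn from 0 to 8. The share of same-sign postnatal slopes ranged from 57.1% to 85.4% and the fetal share from 60.6% to 81%. No paired analysis was possible because replicate numbers follow accession order and each animal gave 1 sample. Signal over background could not be assessed without scanner files, and these were not used here.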

Other observations

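Of the tests in this part, the positions along the fetal to juvenile axis were chosen after the results were seen. The 2 measured genes of the antigen presentation and interferon list, which was too small to test, were both higher in postnatal animals. B2M was at 5.01 ± 0.28 in fetal and 6.97 ± 0.53 in postnatal cortex (log2, mean ± SD, n = 6, limma adjusted p = 2.58e-05). IFIT1 was at 2.25 ± 0.61 and 3.99 ± 0.98 (limma adjusted p = 0.00271).

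Among the immediate early genes, FOS was 2.28 higher and NR4A1 2.30 higher in newborn than in fetal animals (limma adjusted p = 0.000586 and 0.00212), both chosen after their values were seen. Neither gene kept this call without the 24-day animal (postnatal replicate 2), which left only the 1-day animal as newborn. From newborn to juvenile animals FOS and NR4A1 differed by -0.72 and -0.76 (limma adjusted p = 0.58 and 0.689), which did not pass the threshold. DCX, a microtubule protein of migrating neurons and likewise chosen afterwards, fell by 2.31 between the groups (limma adjusted p = 1.7e-05). MAG, a myelin glycoprotein, was 2.57 higher in newborn than in fetal animals (limma adjusted p = 0.00899) and differed by -0.08 from newborn to juvenile (limma adjusted p = 0.996). The call of MAG between newborn and fetal animals was likewise lost without the 24-day animal.

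Other splits of the 12 animals into 6 and 6 tested whether chance could give the counts of the group comparison. Of 100 of the 462 splits, 1 gave as many called rows, the real one, with 3197 against 5 in the highest other split. Every other split mixes fetal and postnatal animals, so the group difference adds to its spread and can lower its count. With 3197 rows against 5, chance is argued against for the rows but not excluded. For the lists 1 of 100 gave as many, again the real one, with 14 against 13 in the highest other split and a median of 5. That highest other split had 4 fetal animals on 1 side. Splits with uneven numbers of fetal animals carry part of the group difference, so their list counts do not show what chance alone gives. Only 100 of the 462 splits were drawn and the margin is 1 list, so chance is not excluded for the count of lists. The count was itself 12 without postnatal replicate 1, 3 or 4 (7 higher and 5 lower without the first, 8 and 4 without the others). It was 0 with an estimated correlation. The list count is thus weak evidence, and a single list call with the preset correlation is weaker still.

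Orders of the ages were tested in the same way. As many rows at an unadjusted p under 0.05 as the 821 of the postnatal trend were reached by 23 of 100 orders (highest 1651), and as many as the 538 of the fetal trend by 24 of 100 (highest 1612), so chance is not excluded for either. The 6 called rows of the postnatal trend were reached by 3 of 100 orders (highest 39).

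Within the postnatal group the position between the fetal and juvenile means followed log2 age (Pearson r = 0.949, exact permutation p = 0.00694, adjusted over 2 groups 0.0139, Spearman's rho = 0.943, exact permutation p = 0.0167, adjusted 0.0333, n = 6). Without the 2 animals farthest from the median log2 age, those of 1 and 24 days, r was 0.573, and 0.71 after quantile normalization. The relation may thus rest on those 2 animals, which the 4 juvenile animals left cannot decide. In the fetal group r was 0.646 (exact permutation p = 0.171) and rho 0.714 (p = 0.136), and r was -0.144 without the 2 farthest.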
